A study of Oryza sativa Japonica Group with 3 samples.

How the data were processed

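Nuclei were isolated from fresh node I tissue of hydroponically grown, untreated rice plants under 12 h of light at 30 °C and 12 h of dark at 26 °C. They were loaded separately by stage on the 10x Genomics Chromium platform with the version 3.1 chemistry, which counts the 3' ends of transcripts with unique molecular identifiers (UMIs), and sequenced on an Illumina NovaSeq, per the labels' protocols. The stated sequencing depth was at least 50000 reads per nucleus. There were 3 samples, 1 library per stage, and the stage of each was taken from its label.

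The deposited values are raw UMI counts per gene and barcode, 1 sparse matrix per library. Per the file headers, the matrices were written by Cell Ranger 7.0.0, while the submitters' processing notes name Cell Ranger 6.1.2, Seurat, Scanpy and the genome build IRGSP-1.0. The roles of Seurat and Scanpy and the rule by which barcodes were kept are not given in the sources used here. The smallest nuclei held 520 UMIs at booting, 790 at flowering and 700 at filling. The 57359 gene identifiers begin with AGIS_Os and are neither of the forms in common use for that build, and the files repeat the identifier in place of a name. The reference table of rice genes used here (assembly ASM3414082v1) matched 0 of them. All 249 genes of the 23 lists fixed in advance (mineral and sugar transporters, starch, nitrogen, cell type markers and others) are listed by other identifiers, and 0 were found. The list medians, the values of named transporters and the naming of clusters were therefore not run. Gene positions and functions were not analysed here.

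Nuclei with 300 or more genes were kept, which removed 0 barcodes. The features hold no plastid or mitochondrial genes, so the limit on organelle UMIs did not apply. Scrublet, run per library through scanpy 1.11.5, marked 0 nuclei, below the 0.5% at which it counts as having worked. Doublets stayed in, and leaving out the 8% of nuclei with the highest scores was an alternative.

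Whole-library levels were UMI counts summed over nuclei and scaled to the same total in every library, as CPM. Ratios were log2 values with a pseudocount of 1 CPM. Folds of named genes are ratios of raw CPM with exact 95% intervals from the Poisson counts. Genes were counted as 2-fold or more apart among those with 20 CPM or more in the higher library, by size and with no test, since nuclei of 1 library are not replicates. The rule for named genes, fixed before the data were examined, took the 10 highest and 10 lowest ratios among genes with a name and with the same direction when every nucleus has equal weight. Because the identifiers carry no names, the 2 highest and 2 lowest identifiers per contrast are given instead.

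For clusters, counts were normalised to 10000 UMIs per nucleus and log-transformed. The 2000 genes most variable within libraries were centred and scaled within each library, and 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 (igraph 0.11.9) followed. Leading genes of a cluster had 20 CPM or more and the largest ratio to all other nuclei, with a pseudocount of 5 CPM. Shares have exact 95% Clopper-Pearson intervals. Clusters of alternatives were matched by the Jaccard index of their nuclei, with 0.5 as the minimum. Within-cluster counts of genes used 12 of the 13 clusters with 200 or more nuclei in each library, without cluster 11, left out by hand after the clusters were seen because its booting sum of 260067 UMIs would have set a lower common total, and genes with 50 CPM or more in the higher library, with all sums thinned to 1 total, beside 50 Poisson draws with no difference.

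The rule by size was tested on simulated data for flowering against booting: it recovered 99.5% of genes simulated at 3-fold in a step on 9677 genes and 99.0% of those at 4-fold in a step on 9650 genes. Both folds lay above the 2-fold cut and the simulated noise was counting error only, so near-complete recovery followed from these settings. Clustering of 5 simulated populations on 9602 genes gave 5 clusters with an adjusted Rand index of 1. Each population had 200 nuclei per library and strongly raised genes of its own, with no free RNA or doublets. That setting does not cover weakly separated clusters such as 5 and 6, which had 0 genes at 4-fold or more. Calculations used numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and pandas 2.3.3. Alternatives fixed in advance changed the scaling, the weight of nuclei, the minimum of genes (700), doublets, the pseudocount (0.1 CPM), the weight of clusters, the Leiden resolution (0.5 and 1.5), scaling over all libraries, the number of variable genes (3000) and the thinning depth (1000 UMIs or none). Added after the data were seen were clustering without the 3059 genes 2-fold or more apart between any pair of libraries (799 of the genes used in the main clustering were among them), clustering each library on its own, and leaving out clusters 5 and 6. The 3059 genes were taken with the pseudocount of 1 CPM and no minimum level. They therefore include genes below the 20 CPM that the counts of genes 2-fold or more apart required.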

Results

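Single nuclei were profiled from node I of rice (Oryza sativa Japonica Group, cultivar Nipponbare, wild type) at booting, flowering and grain filling. Node I is the uppermost node of the culm, where the flag leaf attaches below the panicle, and minerals pass through it to both. The comparison between the stages asks how transcript levels and the mix of nuclei in the node differ as the panicle emerges and the grain fills. Each stage was represented by 1 library, and the batch label differed for every stage (batch 3 at booting, batch 2 at flowering, batch 1 at filling). Stage and batch therefore cannot be told apart, no test between stages was possible, and every interval given here covers counting error only.

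The libraries held 31265 barcodes at booting, 30993 at flowering and 31842 at filling. The total UMI count was 34512640 at booting, 53366245 at flowering and 47425890 at filling. The booting library was the shallowest, with a median of 806 UMIs and 599 genes per nucleus, against 1492 UMIs and 1041 genes at flowering and 1238 UMIs and 854 genes at filling. After every nucleus was thinned to 500 UMIs, which left out 0 nuclei in each library, the median number of genes per nucleus was 404 at booting, 420 at flowering and 410 at filling. The 10 most abundant genes took 6.82% of the UMIs at booting, 7.51% at flowering and 7.32% at filling. At least 1 UMI was counted for 30281 genes at booting, 31017 at flowering and 31069 at filling.

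Between booting and flowering, 319 of 10219 genes stood 2-fold or more higher at flowering and 378 stood 2-fold or more lower, as counts by size with no test behind them. AGIS_Os08g013680 was at 1.22 CPM at booting (95% Poisson interval 0.877 to 1.64) and at 111 CPM at flowering (108 to 114), a 91.4-fold higher level at flowering (exact interval 67.6 to 127). AGIS_Os11g022470 was 111-fold higher at flowering (71.0 to 185), at 61.1 CPM against 0.551 CPM. In the flowering library, its level in cluster 13 was 1100 CPM and the median over clusters was 20.9 CPM; it was also among the genes that led cluster 13. In the other direction, AGIS_Os04g020410 was at 93.7 CPM at booting and at 0.131 CPM at flowering, from 3235 and 7 UMIs, a 715-fold higher level at booting (346 to 1780). At booting it was counted in each of the 13 clusters with 200 or more nuclei per library, at 30.3 to 220 CPM. AGIS_Os11g027850 was 48.3-fold higher at booting (40.2 to 58.5), at 107 CPM against 2.21 CPM, and was highest in cluster 9 at 788 CPM. Across 19543 genes with a mean of 1 CPM or more, the log2 levels of the libraries had a Pearson r of 0.954 and a Spearman rho of 0.957. These are correlations across genes, which are not independent replicates.

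Flowering and filling were the closest pair. Of 9892 genes, 96 were 2-fold or more higher at filling and 74 were 2-fold or more lower, and the log2 levels had a Pearson r of 0.982 across genes. AGIS_Os02g042820 was at 44.5 CPM at filling and 2.64 CPM at flowering, a 16.8-fold higher level (14.2 to 20.1). Its level at filling was 200 CPM in cluster 9 and 31.5 CPM in the median cluster. AGIS_Os08g027130 was 18.7-fold higher at filling (14.7 to 24.1), at 24.9 CPM against 1.33 CPM, and also had its highest level in cluster 9, at 74.6 CPM. AGIS_Os03g041490 was 5.69-fold higher at flowering than at filling (5.05 to 6.43), at 37.8 CPM against 6.64 CPM, and stood at 13.3 CPM at booting. AGIS_Os10g023020 was 3.91-fold higher at flowering (3.62 to 4.23), at 65.9 CPM against 17 CPM. In both libraries its highest level was in cluster 7, at 156 CPM at flowering and 41.6 CPM at filling.

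Booting and filling were the farthest apart. Of 10378 genes, 535 were 2-fold or more higher at filling and 606 were 2-fold or more lower. The counts at 4-fold or more were 117 and 131, against 9 and 1 between filling and flowering. The Pearson r across genes was 0.930. AGIS_Os08g013680 had a level of 115 CPM at filling, close to its level at flowering, and was 94.3-fold higher than at booting (69.7 to 131). AGIS_Os03g015680 was at 0.174 CPM at booting, 17.9 CPM at flowering and 53.2 CPM at filling, a 306-fold higher level at filling than at booting (140 to 835). AGIS_Os11g027850 was at 0.19 CPM at filling, a 562-fold higher level at booting (296 to 1230). AGIS_Os04g020410 was at 2.95 CPM at filling, so that its level at flowering was the lowest of the 3 libraries. The plot of whole-library levels shows these genes in all 3 libraries. Each comparison rests on 1 library per stage and has no replicate check.

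**Figure D1:**
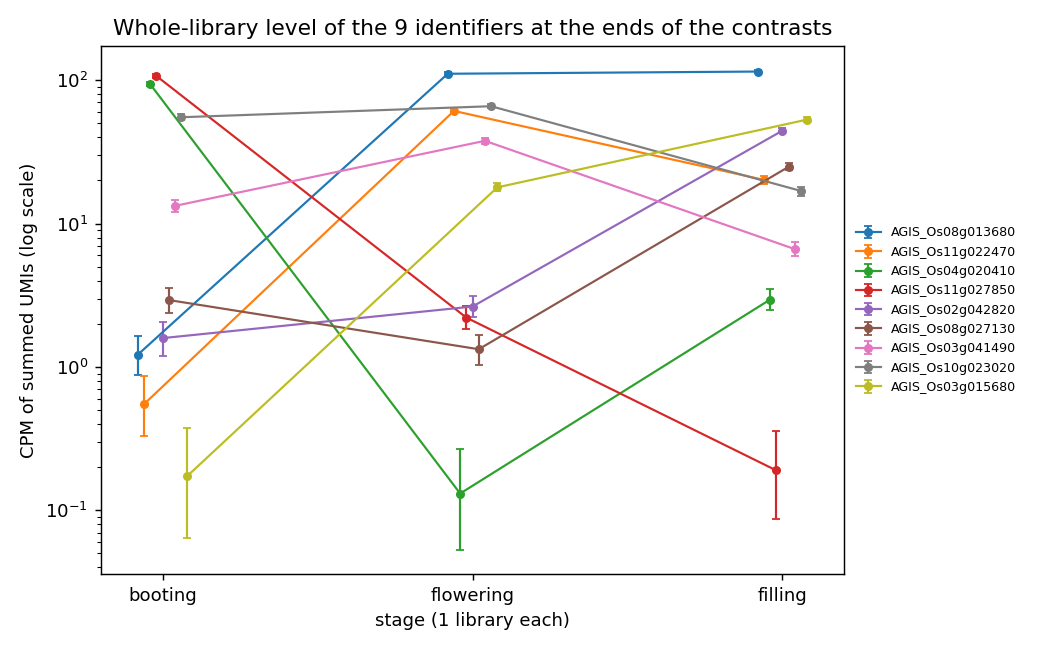
Level of the 9 gene identifiers at the ends of the 3 contrasts, in CPM of summed UMIs on a log axis, against stage with 1 library each. Points are library values and bars are exact 95% Poisson intervals of the counts. AGIS_Os04g020410 and AGIS_Os11g027850 are near 100 CPM at booting (93.7 and 107) and below 3 CPM in the other libraries, and AGIS_Os08g013680 runs the other way, from 1.22 to 111 and 115 CPM.

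The 94100 nuclei formed 14 clusters, which keep their numbers here because the identifiers in the files could not be paired with the marker lists. Clusters 13 and 14 were the most distinct, with 288 and 412 genes that were 4-fold or more above all other nuclei together. Cluster 14 was small, with 30 nuclei at booting, 42 at flowering and 37 at filling. It was led by AGIS_Os09g024220, at 14300 CPM against 6.47 CPM in the other clusters. The leading gene was AGIS_Os04g011860 in cluster 1, AGIS_Os09g032650 in cluster 2, AGIS_Os02g041250 in cluster 3, AGIS_Os10g015960 in cluster 4, AGIS_Os11g040100 in cluster 7 and AGIS_Os12g014480 in cluster 8. In the remaining clusters it was AGIS_Os04g026010 in cluster 9, AGIS_Os11g006190 in cluster 10, AGIS_Os05g041780 in cluster 11, AGIS_Os04g008810 in cluster 12 and AGIS_Os11g022470 in cluster 13. These genes lead over all libraries together: of the 12 clusters without 5 and 6, the same gene led at booting alone in 6, at flowering in 8 and at filling in 9. At booting AGIS_Os11g022470 was at 12.0 CPM in cluster 13, where AGIS_Os06g033710 led at 514 CPM, and AGIS_Os05g041780 was at 11.5 CPM in cluster 11. Clusters 5 and 6 had 0 genes at 4-fold or more, and cluster 6 held the shallowest nuclei, with a median of 590 UMIs at booting, 882 at flowering and 809 at filling. Clusters 3, 4 and 11 resembled one another, with correlations across genes of 0.70 between 3 and 4 and of 0.57 between 11 and either of these. Scrublet marked 0 nuclei as doublets in each library, which is read as a caller that did not work, so doublets stayed in.

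Cluster 6 was the largest, and its share differed by more percentage points between the booting library and the others than that of any other cluster. It held 46.6% of nuclei at booting (95% Clopper-Pearson interval 46.0 to 47.1), 23.8% at flowering (23.4 to 24.3) and 23.8% at filling (23.4 to 24.3). When the genes 2-fold or more apart between any pair of whole libraries were kept out of the clustering, the matching set held 47.4%, 24.6% and 25.4%. With genes scaled over all libraries, cluster 6 had no match (Jaccard index 0.461). The share depends on which low-UMI barcodes a library holds, and the smallest barcodes had 520 UMIs at booting, 790 at flowering and 700 at filling. The median of cluster 6 at booting, 590 UMIs, lay below the minima of both other libraries. In the bin of 792.6 to 855.9 UMIs, the lowest above all the minima, cluster 6 was least frequent at booting. There it held 477 barcodes and the other clusters 586 at booting, against 2736 and 558 at flowering and 1229 and 939 at filling. The same order of booting below both others held in each higher bin up to 2150.7 UMIs. From 997.9 to 1077.6 UMIs, for example, the counts were 117 and 898 at booting, 624 and 917 at flowering, and 428 and 1443 at filling. With every nucleus thinned to 500 UMIs and assigned to the nearest cluster profile, cluster 6 took 44.5%, 23.1% and 22.1%. That run kept every barcode and returned 90.0%, 88.4% and 76.3% of cluster 6 to its own profile, so it cannot remove the difference in minima. The filling to booting ratio was 0.512 among all nuclei and 1.6 for the matching cluster among nuclei with 700 genes or more, a minimum that by itself kept 2.8% of cluster 6 at booting, 41.5% at flowering and 21.4% at filling. Among all nuclei, cluster 2 held 3.47% at booting (3.27 to 3.68), 5.1% at flowering (4.86 to 5.35) and 6.54% at filling (6.28 to 6.82), and cluster 13 held 2.1% (1.94 to 2.26), 3.14% (2.95 to 3.34) and 3.73% (3.53 to 3.95). Cluster 9 held 4.69%, 6.28% and 8.22%, and cluster 8 held 6.7%, 10.4% and 10.4%. Cluster 7 held 9.53%, 13.4% and 10.8%, and cluster 10 held 4.13%, 4.56% and 4.33%. The large share of cluster 6 at booting lowers every other share there. Of the nuclei outside clusters 5 and 6, cluster 2 held 6.72% at booting and 8.73% at filling, cluster 13 held 4.07% and 4.98%, cluster 9 held 9.08% and 11%, and cluster 8 held 13.0% and 13.9%. For clusters 7 and 10 the direction turned, with 18.5% and 8.0% at booting against 14.4% and 5.77% at filling. Each of these 6 clusters was found again without the stage-different genes, with a Jaccard index of 0.63 to 0.839, and the filling to booting ratio among all nuclei was then 1.85 for cluster 2, 1.56 for cluster 13, 1.4 for cluster 9, 1.48 for cluster 8, 1.24 for cluster 7 and 1.23 for cluster 10. Cluster 9 fell below the minimum Jaccard index of 0.5 in other runs: 0.471 at resolution 1.5, 0.495 with genes scaled over all libraries, 0.428 without the highest doublet scores, 0.441 with 700 genes or more per nucleus, 0.433 with 3000 variable genes and 0.456 when booting was clustered alone. Cluster 10 did so at resolution 0.5 (0.388) and with genes scaled over all libraries (0.303). Among nuclei with 700 genes or more the ratio was below 1 for cluster 7 (0.817), cluster 8 (0.959) and cluster 10 (0.847), and it was 1.11 for cluster 13 against 1.78 among all nuclei. With genes scaled over all libraries, where most booting nuclei formed clusters of their own, it was 70.1 for cluster 7 and 28.9 for cluster 8, against 1.13 and 1.55. For cluster 14 the shares of 0.096%, 0.136% and 0.116% had overlapping intervals, so a difference was not detectable at this number of nuclei, and the cluster was not separated without the stage-different genes.

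Clusters 3, 4 and 11 could not be compared in size. Cluster 11 held 231 nuclei at booting, 1975 at flowering and 2878 at filling, and cluster 3 held 3096, 2457 and 1579. The booting nuclei of cluster 11 were shallow, with a median of 830 UMIs against 2288 at flowering and 1815.5 at filling. Without the stage-different genes, 79.8% of cluster 3 and 86.3% of cluster 11 fell into 1 set. That joint set held 11% of nuclei at booting (10.7 to 11.3), 15.9% at flowering (15.4 to 16.3) and 17.3% at filling (16.8 to 17.7). A cluster that comes mostly from 1 or 2 libraries, as cluster 11 did, may stand for those libraries and not for a type of nucleus.

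**Figure D2:**
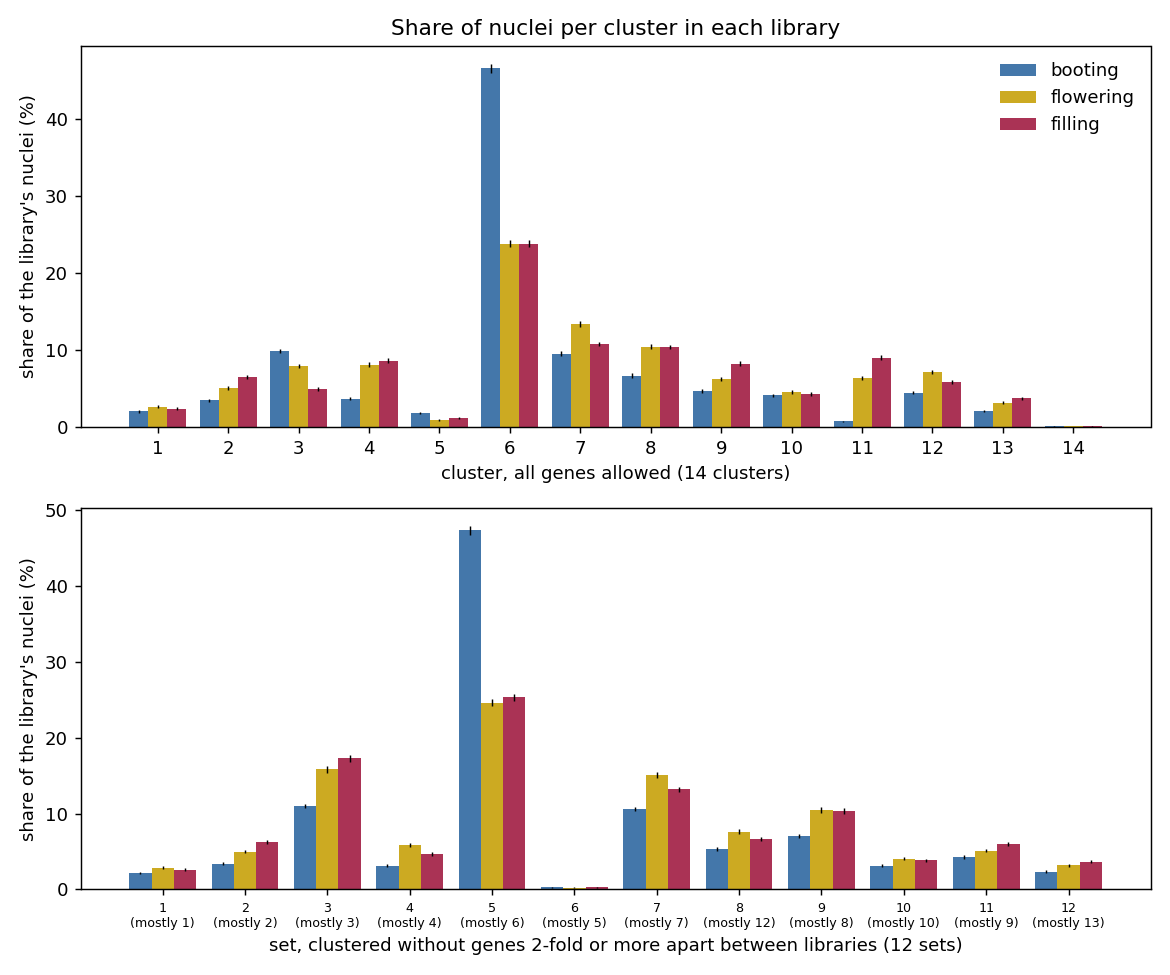
Share of each library's nuclei per cluster, in percent, for the 14 clusters of the main clustering (top) and for the 12 sets found without genes 2-fold or more apart between libraries (bottom, with the main cluster that gives most of each set). Bars are the 3 libraries and error bars exact 95% binomial intervals. Cluster 6 stands at 46.6% at booting and 23.8% in both other libraries, and its matching set at 47.4%, 24.6% and 25.4%.

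**Figure D3:**
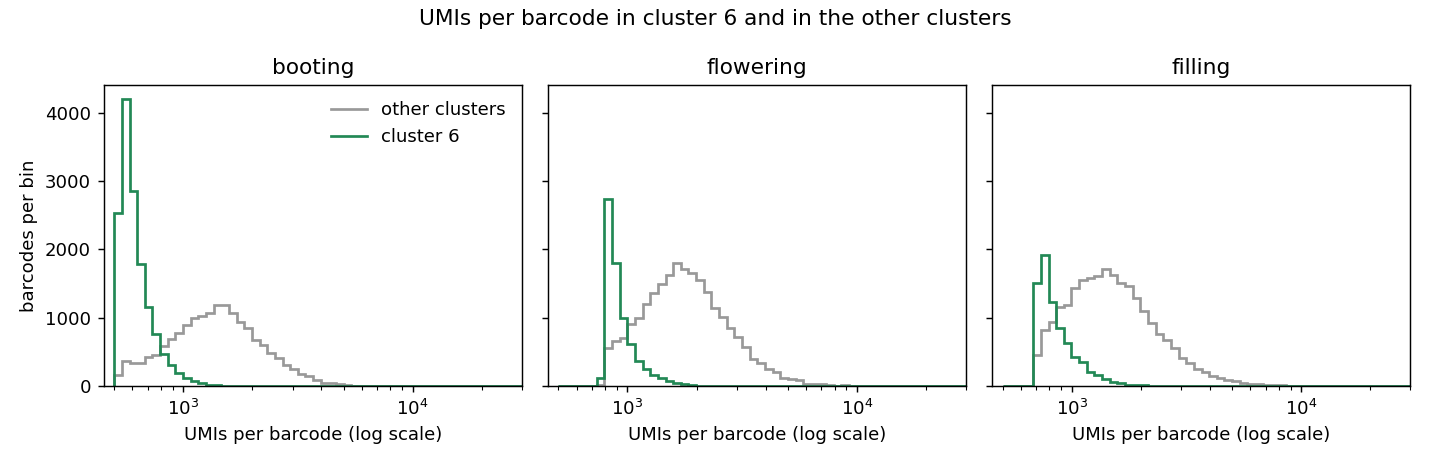
Number of barcodes per bin of UMIs per barcode (log axis) in each library, for cluster 6 and for all other clusters together. Cluster 6 lies at the lower end in each library, with medians of 590, 882 and 809 UMIs at booting, flowering and filling.

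Within clusters the order of the 3 contrasts was the same as in the whole libraries. In each of 12 clusters, summed UMIs were thinned to 664583 per library so that counts of genes could be compared. Between filling and flowering, 144 to 349 genes per cluster were 2-fold or more apart, which was 2.76% to 6.12% of the genes compared. Between flowering and booting the range was 418 to 816 genes, and between filling and booting 726 to 1196. Poisson draws with no difference between the libraries gave a mean of 19.7 to 26.4 such genes for filling and booting, with a highest draw of 42. The draws hold counting error only. Counts above them therefore include any difference between 2 separately made libraries and do not measure an effect of stage. In the clustering as reported, cluster 9 had the highest count between filling and booting, 1196 of 6012 genes compared (19.9%), with 583 higher at filling and 613 lower, while cluster 12 had the highest share, 1124 of 5495 (20.5%). At resolution 0.5 their counts were 1278 and 1115. Without the 8% highest doublet scores cluster 9 had no match. Cluster 12 then had 901 genes, below clusters 13 (1068), 3 (1018), 7 (1016) and 10 (941), so the ranking depended on the processing. Between filling and flowering cluster 9 had 349 of 5700 genes (6.12%). Of the 4207 genes that were 2-fold or more apart between filling and booting in at least 1 of the 12 clusters, 2192 were so in 1 cluster and 546 in 6 or more. The same counts between filling and flowering were 1501, 1084 and 47. The genes counted in 1 cluster include those that the draws attribute to counting error. Cluster 11 was left out of these counts, by a choice made after the clusters were seen, because its UMIs at booting summed to only 260067 and would have lowered the common total.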

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

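This part was chosen after the values were seen. Between flowering and booting, 2 genes stood 4-fold or more higher in 1 cluster and 4-fold or more lower in another, among 12 clusters (without cluster 11) and at 50 CPM or more in the higher library. AGIS_Os05g043220 was at 501 CPM at flowering and 85.0 CPM at booting in cluster 1, a log2 ratio of 2.55, and at 13.0 and 61.4 CPM in cluster 3, a log2 ratio of -2.15. It was the leading gene of cluster 1 at flowering, where AGIS_Os07g005420 led at booting, so its level there is tied to what marks the cluster. AGIS_Os12g031410 was at 73.2 and 12.9 CPM in cluster 4, a log2 ratio of 2.42, and at 13.8 and 60.2 CPM in cluster 13, a log2 ratio of -2.05. The difference between clusters was not tested, since each cluster has 1 library per stage. Clusters 3 and 4 had no match without the stage-different genes (Jaccard index 0.372 and 0.439) or when booting was clustered alone (0.376 and 0.324), so different nuclei can stand behind their values in the 2 libraries.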

How the results depend on the processing

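The clusterings without stage-different genes and of each library alone, and the values without clusters 5 and 6, were chosen after seeing the data. The counts of genes 2-fold or more apart in whole libraries stayed within 1.5 times of the reported ones in all 42 alternative values. Within clusters, all 21 alternative counts that were run did so. Those covered only filling over booting, at resolution 0.5, with genes scaled over all libraries and without the 8% highest doublet scores. Cluster 5 had no such count, and the other contrasts and settings were not run within clusters. The 12 log2 ratios of named genes kept their sign in every alternative run, and the largest shift was 2.28 with a pseudocount of 0.1 CPM and 0.34 among the others. The kept sign was near certain by choice. These genes were picked at the ends of the contrasts, and the same direction at equal weight per nucleus was required. Shares of nuclei did depend on the processing, and are given where the cluster had a match. The filling to booting ratio among all nuclei was 1.17, 1.89, 0.501, 2.31, 0.661, 0.512, 1.13, 1.55, 1.76, 1.05, 12.2, 1.29 and 1.78 for clusters 1 to 13 in turn. With 700 genes or more per nucleus it was 0.779 for cluster 1, 1.27 for 2, 0.303 for 3, 1.5 for 4, 1.6 for 6, 0.817 for 7, 0.959 for 8, 0.847 for 10, 29.1 for 11, 0.792 for 12 and 1.11 for 13. Without clusters 5 and 6 it was 0.809 for cluster 1, 1.3 for 2, 0.345 for 3, 1.59 for 4, 0.78 for 7, 1.07 for 8, 1.21 for 9, 0.722 for 10, 8.42 for 11, 0.891 for 12 and 1.23 for 13. Both settings take more nuclei from the booting library than from the others. With each library clustered on its own it was 0.887 for cluster 1, 0.75 for 6, 1.0 for 7, 0.99 for 10 and 1.55 for 12. With genes scaled over all libraries, where most booting nuclei formed clusters of their own, it was 2.24 for cluster 2, 70.1 for 7 and 28.9 for 8. For cluster 11 it was at least 985, against a floor of 3 nuclei at booting, where the matching cluster had 0. At resolution 1.5 it was 0.62 for cluster 3, 2.07 for 4, 1.42 for 7, 0.963 for 10 and 1.03 for 12, and at resolution 0.5 it was 0.561 for 6, 1.28 for 7, 1.44 for 9 and 1.17 for 12. Without the 8% highest doublet scores it was 0.546 for cluster 3, 2.04 for 4, 1.38 for 7, 0.905 for 10, 25.6 for 11 and 1.0 for 12. With 3000 variable genes it was 1.45 for cluster 7, 0.934 for 10 and 27 for 11. Without stage-different genes it was 0.535 for cluster 6, 1.24 for 7, 1.4 for 9 and 1.23 for 10, while clusters 3, 4, 5 and 11 had no match. The cause of the other shifts was not tested. Of the remaining shares, 31 alternative values lay within the counting interval. Median genes per nucleus were 599, 1041 and 854 at booting, flowering and filling with no thinning, and 737, 761 and 737 at 1000 UMIs, a depth that left out 18453, 7636 and 10763 nuclei.

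The alternatives for gene list medians, with their filters on low values, were not run because no list gene was found, and keeping all deposited barcodes changes nothing because the minimum of genes removed none. No paired analysis was possible because each stage has 1 library and no test was run. The minimum of 700 genes kept 2.8%, 41.5% and 21.4% of cluster 6 at booting, flowering and filling, so its turned ratio follows from the cut. The ratio of cluster 6 among all nuclei, 0.512, likewise depends on the unequal UMI minima of the libraries.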

Other observations

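The test of chance for neighbouring identifiers was written after its result was seen, and the clustering without stage-different genes was added after seeing the data. Also chosen after the results were seen were the sum of clusters 3 and 11, the leading sets gene by gene, the spread over leading sets in cluster 6, the nuclei kept at 700 genes, and the checks of the floor of peaked genes and of the pairs open to a copied gene. The 20 genes that led cluster 4 in the flowering library summed to 986 CPM in the whole booting library, 2964 at flowering and 4749 at filling, but AGIS_Os01g060240, named because it was the highest, took 75.0% of the sum at filling. Without that gene the sum was 1.76 times as high at flowering as at booting and 0.828 times as high at filling as at flowering, and over the 20 genes the median log2 ratios were 0.88 and -0.14. The 20 genes that led cluster 11 summed to 575.6, 1509 and 2609 CPM, and all 20 were higher at filling than at booting, with a median log2 ratio of 2.6. The 20 genes that led cluster 3 ran the other way, at 5725, 2925 and 2290 CPM, with 3 of the 20 higher at filling than at booting and 12 at 2-fold or more lower. These sums need no assignment of nuclei in the booting and filling libraries, but their genes do rest on the clustering. The genes were chosen in clusters formed from all 3 libraries together, in part with genes that differ between libraries. Cluster 11 held 231 nuclei at booting against 1975 at flowering, so lower levels of its leading genes at booting are in part built into the choice. Because clusters 3, 4 and 11 resemble one another, a shift of levels within 1 kind of nucleus and a change in the number of nuclei would both appear in these sums.

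A pattern a reader would want to follow up is cluster 11, whose share was 12.2 times larger at filling than at booting. The size of that ratio is not settled: it was 8.42 among nuclei outside clusters 5 and 6, 12.3 at resolution 1.5, 25.6 without the highest doublet scores, 27 with 3000 variable genes and 29.1 with 700 genes or more. The cluster had no match when booting was clustered alone (Jaccard index 0.0346). With genes scaled over all libraries the ratio was at least 985. Most booting nuclei formed clusters of their own in that run, so this value reflects the parting of libraries and is no estimate of the ratio. With every nucleus thinned to 500 UMIs and assigned to the nearest cluster profile the ratio was 32.9. A ratio that high had been set in advance as evidence against the depth of the libraries. The profiles, however, came from the clustering at unequal depth, and 39.0% of cluster 11 at booting and 89.1% at filling returned to it. The test therefore cannot decide whether depth shaped the cluster itself. Whether genes that differ between stages decide who is in the cluster stays open. When genes 2-fold or more apart between libraries were kept out, the best matching set had a ratio of 1.57, below the bound of 2 set in advance. It joined most of clusters 3 and 11 with nuclei of other clusters, however, and had a Jaccard index of 0.302. Clusters 3 and 11 simply added, with no genes kept out, already had a ratio of 1.32, so the joining fixed the outcome. The batch cannot be told apart from the stage in this design, and the stage remains an untested biological explanation.

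The low-UMI barcodes of cluster 6 made up 46.6% of the booting library and 23.8% of each of the others. The larger share at booting rests on barcodes with fewer UMIs than the other libraries hold, whose minima were 790 at flowering and 700 at filling. Of 2108 booting nuclei of other clusters thinned to 590 UMIs, 8.25% went to the profile of cluster 6. At flowering and filling 3.92% and 9.34% did so. These values lie below the bound set in advance as evidence against shallow nuclei of the other clusters. The thinned nuclei, however, were those that the clustering had already placed outside cluster 6. Of them, 79.1% at booting, 83.6% at flowering and 71.3% at filling went to their own cluster's profile. The values therefore hold for such nuclei and for assignment to known profiles only, and do not cover shallow nuclei with weak marks. Clusters were not formed again from thinned nuclei, so where shallow nuclei would fall in the clustering itself was not tested. Droplets that hold only free RNA, shallow nuclei with weak marks and nuclei of a mixed or undefined kind cannot be told apart. The genes leading other clusters stood at 0.871 times their whole-library level in cluster 6 at booting, 0.85 at flowering and 0.853 at filling, as free RNA would give, but their counts varied between barcodes 1.33 times as much as binomial sampling at booting, 1.29 at flowering and 1.54 at filling (medians over 12 leading sets). The value at filling passes the 1.5 set in advance as evidence against free RNA, by less than the spread over the sets (1.38 to 2.64), and those at booting and flowering lie between 1.5 and the 1.2 set as its upper limit. The same 1.5 had also been set as a part of what shallow nuclei would give. The ratio of 1.6 among nuclei with 700 genes or more decides nothing here, because that minimum kept 2.8% of cluster 6 at booting, 41.5% at flowering and 21.4% at filling. The ratio of 0.512 among all nuclei decides as little, because it rests on the unequal UMI minima of the libraries. In the UMI range that all libraries hold, cluster 6 was not more frequent at booting. There it was least frequent at booting in each bin from 792.6 to 2150.7 UMIs. No biological explanation was tested.

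With genes scaled over all libraries, it was mainly the booting nuclei that parted: 5 of 18 clusters drew 98.0% or more of their share-adjusted nuclei from booting. Of the other clusters, 1 drew 92.9% from flowering and 1 drew 94.4% from filling, and in the rest the highest share of a library was 38.4% to 65.7%. Free RNA of each library added to all nuclei stays open. Of the 200 genes most different between flowering and booting, 60.0% had a highest cluster 4 times or more above the median cluster. That result had been set as evidence against free RNA, but a peak in 1 cluster does not exclude a floor in all of them. Of the 120 genes with such a peak, 65 (54.2%) stood in their lowest cluster at 2 times or more the median cluster of the other library with the pseudocount of 1 CPM added. The count was 28 of 65 (43.1%) for genes higher at booting and 37 of 55 (67.3%) for genes higher at flowering. AGIS_Os11g022470, for example, was at 1100 CPM in cluster 13 at flowering and still at 16.5 CPM in its lowest cluster, against a median of 0 at booting. Free RNA, the batch and a difference in every kind of nucleus cannot be told apart here.

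Some leading genes of a cluster had neighbouring identifiers. Among the 50 leading genes of each of 12 clusters there were 25 pairs with adjacent serial numbers, against a mean of 0.805 and a highest of 6 in 10000 draws of genes matched on expression. The pairs held 48 genes, so most leading genes were in no pair. In 80.0% of pairs the lower gene had over 25% of the level of the higher one, which had been set as evidence against reads of 1 gene being counted also for its neighbour. The choice of leading genes in part fixed this outcome: a copy at 10% of the higher gene could itself have been a leading gene in 12 of the 25 pairs. In 9 of those 12 the lower gene was over 25%, and in 0 it was at 10% or less, but a larger share of copied reads is not excluded. Copies side by side on the chromosome and gene models that split 1 gene into a pair would be told apart by gene positions and sequences, which were not analysed.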
